A study of Mus musculus with 18 samples.

How the data were processed

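The series measured RNA of hepatocytes from Mtdh knockout (KO) and wild-type (WT) mice treated with TNFa, TGFb or conditioned medium (CM) of Kupffer cells that had received Py8119-EVPs. Each of the 6 groups holds 3 libraries, 18 in all, and the series has no untreated group. Per the labels' protocols, total RNA was extracted with an RNeasy kit and libraries were made with the QIAseq FastSelect kit against ribosomal RNA and the PrepX protocol. Doses, treatment times, sex of the mice and the part of Mtdh that was removed are not given in the sources used here.

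The table holds 1 normalized signal per gene and library, which the authors deposited as DESeq2-normalized values, per the file name. Per the submitters' processing notes, Partek, STAR 2.7.8a and DESeq2 were used with the mm39 build, without order or settings. The deposited table lists 16873 genes, each protein-coding, of which 48 were at 0 in all 18 libraries and 12338 were above 0 in all of them. Low values were mostly multiples of 1 step per library, which was taken as the value of 1 read (0.688 to 1.25), but not for nearly all values. Of values up to 200 reads, between 67.4% and 73.6% per library lay within 0.01 reads of a whole multiple, and up to 77.0% within 0.05 reads. Of values up to 20 reads, up to 83.0% lay within 0.05 reads. Whole reads were therefore not recovered.

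Depth was estimated as the sum of the deposited values divided by that step. It ranged from 19.4 to 35.6 M reads on the protein-coding genes (median 23.4). By group it was 29.9, 28.4 and 30.0 for TNFa WT, 29.1, 20.3 and 21.2 for TNFa KO, 23.7, 20.4 and 19.4 for TGFb WT, 28.4, 23.1 and 21.5 for TGFb KO, 21.8, 23.0 and 21.3 for CM WT and 35.6, 26.6 and 24.2 for CM KO. Between 14062 and 15234 genes had at least 1 estimated read. Replicates of a group differed by more than counting error, with a mean chi-square per gene between 11.8 and 54.5 for genes with at least 100 reads in a pair, and a correlation of log2 values between 0.937 and 0.961. The 10 most abundant genes held between 12.6% and 19.9% of a library's values.

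Values were put on the log2 scale after 1 was added. Genes with a value of at least 10 in at least 3 libraries were tested, 14455 in number. A limma-trend model (limma 3.58.1 in R 4.3.3) with 6 group means and no block was fitted to the 18 libraries, with 12 residual and 17.0 prior degrees of freedom. Benjamini-Hochberg adjusted p-values below 0.05 were called. The comparisons were KO against WT within each treatment and averaged over treatments, each pair of treatments within WT, and the difference of the KO effect between treatments (pairwise and as an F-test). The p-values measure spread between libraries, not mice if 1 preparation supplied a genotype. Whether it did, or whether 1 number marks 1 mouse, is not given, so libraries were not paired.

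Camera of limma tested 37 gene lists, fixed by hand from general knowledge of liver biology. It used a preset correlation of 0.01 and again one estimated per list. P-values were adjusted over a comparison's lists, and calls within a list also over the list alone. List p-values below use the preset. Those from the estimate were often far larger and are printed where they did not pass. The lists, grouping, tests, naming rule and, except for 3, the alternatives were written before the data were examined.

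Genes were named by rule. Mtdh was reported in each library. Named next were up to 8 genes with the largest rise and 8 with the largest fall among called genes with a mean value of at least 50 whose KO and WT (or treatment) libraries did not overlap, which chance gives for 10% of genes in a comparison of 3 against 3. Predicted and unnamed genes and pseudogenes were left out. From each list up to 3 called members with the smallest p-values could be named, and for the interaction the 8 genes with the smallest p-values. The text leaves out some of these.

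The alternatives tried were a pseudocount of 0.5 or 5, no filter, a filter on a mean of at least 50, recomputed median-of-ratios scaling, quantile normalization, fits of only the groups compared, the replicate number as a block, a correlation within genotype and replicate number, means per genotype and replicate number, an estimated list correlation and leaving out each library. Scaling to equal totals, limma-voom on estimated reads and library weights were added after the data were seen. In simulated data with 200 changed genes, the model called 177 for KO against WT with TNFa, 156 changed and 21 (11.9%) unchanged. For the average it called 194 (14 or 7.22% unchanged), and for the interaction 129 (4 or 3.10%). A list shifted by 0.5 was called and 0 of 36 unchanged lists were. This does not settle error control for real lists, with estimated correlations up to 0.85. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.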

Results

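Mtdh, the gene removed in the knockout mice (chromosome 15, 34082840 to 34145770 on mm39, as listed in the deposited table), was read in every library. With TNFa the deposited normalized value was 749, 829 and 581 in the 3 KO libraries and 13063, 13037 and 12393 in the 3 WT libraries, with TGFb it was 973, 970 and 933 in the 3 KO libraries and 13598, 13725 and 12873 in the 3 WT libraries, and with conditioned medium (CM, conditioned by Kupffer cells treated with Py8119-EVPs) it was 747, 720 and 864 in the 3 KO libraries and 12253, 10063 and 12012 in the 3 WT libraries. The KO mean was 5.61% of the WT mean with TNFa, 7.15% with TGFb and 6.79% with CM, and Mtdh fell with log2 fold changes of -4.17 ± 0.11, -3.80 ± 0.11 and -3.88 ± 0.11 in turn (limma adjusted p = 1.7e-22, 2.3e-21 and 1.3e-21). Values after a gene name below are log2 fold changes with their standard error from groups of 3 libraries, unless stated otherwise, and a gene rose or fell where its limma adjusted p was below 0.05.

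**Figure D1:**
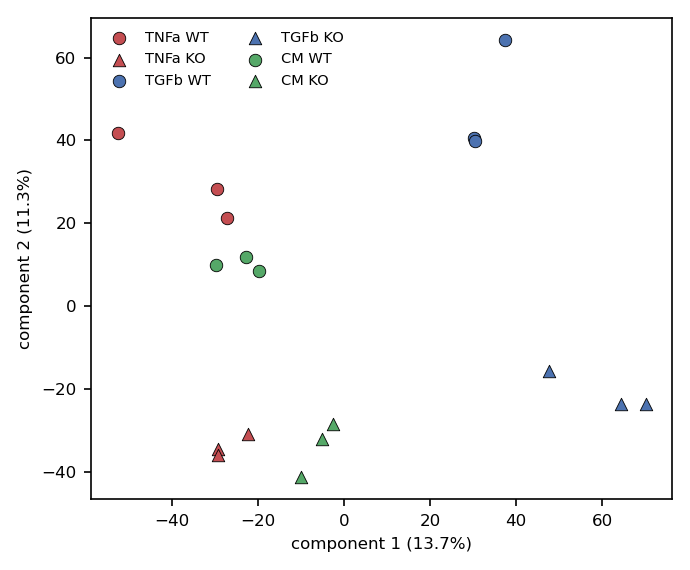
First 2 principal components of the 18 libraries, holding 13.7% and 11.3% of the variance. TGFb libraries lie to the right of TNFa and CM libraries, and KO libraries lie below WT libraries within each treatment.

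With TNFa, KO libraries differed from WT libraries in macrophage genes, in metabolic enzymes and in a few genes of large change. The largest rises were in Gng2 (a G protein gamma subunit, 3.44 ± 0.53) and Tlr13 (an endosomal receptor for bacterial RNA, 3.43 ± 0.75, 4.43 without TNFa WT 1, 1.66 without TNFa WT 2 and 4.19 without TNFa WT 3). After Mtdh, the largest falls were in Rsc1a1 (a regulator of solute carriers, -3.58 ± 0.81, -4.54 without TNFa KO 1), Nnt (the mitochondrial transhydrogenase, -3.29 ± 0.75) and Csad (an enzyme of taurine synthesis, -3.26 ± 0.24). The table holds 2 overlapping Nnt gene models that share reads, which leaves the Nnt value uncertain. Across 14455 genes, 1141 passed, 606 higher and 535 lower in KO (499 and 284 without TNFa WT 3).

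Of the Kupffer cell and macrophage markers, genes of the resident liver macrophage, 19 were tested, 13 rose, 0 fell and 6 did not pass (15 and 0 adjusted over the list alone). Their median was 1.36 (list test adjusted p = 1.4e-13), and members that passed included Lyz2 (1.50 ± 0.13), Cd5l (2.29 ± 0.21) and Slc40a1 (0.90 ± 0.11). Of the sinusoidal endothelial markers, genes of the vessel lining, 19 were tested, 7 rose, 0 fell and 12 did not pass (10 and 0 adjusted over the list alone). Their median was 0.69 (list test adjusted p = 5.6e-07), and members that passed included Cdh5 (0.99 ± 0.12) and Fcgr2b (1.96 ± 0.32). Among periportal genes, which hepatocytes near the portal vein express most, 19 were tested, 10 rose, 1 fell and 8 did not pass (14 and 2 adjusted over the list alone). Their median was 0.77 (list test adjusted p = 3.1e-12), and members that passed included Hal (1.80 ± 0.14), Pck1 (1.17 ± 0.11) and Arg1 (0.91 ± 0.10). Among enzymes of drug and xenobiotic metabolism 36 were tested, 14 rose, 3 fell and 19 did not pass (17 and 3 adjusted over the list alone). Their median was 0.29 (list test adjusted p = 4.9e-07), and members that passed included Cyp2a5 (0.82 ± 0.09) and Fmo5 (1.11 ± 0.12). For bile acid synthesis and transport 26 were tested, 11 rose, 2 fell and 13 did not pass (15 and 4 adjusted over the list alone). Their median was 0.46 (list test adjusted p = 9.6e-06), and members that passed included Akr1d1 (1.06 ± 0.10) and Slco1b2 (0.79 ± 0.08).

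Of the NRF2 antioxidant genes, which respond to oxidative stress, 25 were tested, 8 rose, 3 fell and 14 did not pass (10 and 3 adjusted over the list alone). Their median was 0.31 (list test adjusted p = 5.1e-04), and members that passed included Txnrd1 (0.65 ± 0.08), Slc7a11 (0.80 ± 0.11) and Gclc (0.65 ± 0.09). Cholesterol synthesis genes, which make sterols from acetyl-CoA, were lower, and of these 25 were tested, 0 rose, 9 fell and 16 did not pass (1 and 12 adjusted over the list alone). Their median was -0.33 (list test adjusted p = 4.9e-07, adjusted p = 0.084 with an estimated correlation), and members that passed included Fdps (-0.73 ± 0.11) and Nsdhl (-0.51 ± 0.11). Of the interferon-stimulated genes, an antiviral set, 35 were tested, 0 rose, 8 fell and 27 did not pass (1 and 10 adjusted over the list alone). Their median was -0.36 (list test adjusted p = 5.2e-06, adjusted p = 0.23 with an estimated correlation), and members that passed included Usp18 (-0.65 ± 0.11). Among genes of the unfolded protein and amino acid stress response 27 were tested, 0 rose, 7 fell and 20 did not pass (1 and 7 adjusted over the list alone). Their median was -0.21 (list test adjusted p = 1.7e-04), and members that passed included Vldlr (-0.46 ± 0.08) and Ddit4 (-0.75 ± 0.16).

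Hepatocyte identity genes counted 12 rises and 2 falls of 34 tested, with 20 not passing (13 and 3 adjusted over the list alone, median 0.20, adjusted p = 1.1e-05, adjusted p = 0.10 with an estimated correlation), with Tdo2 (0.99 ± 0.09). Pericentral hepatocyte genes counted 8 rises and 2 falls of 19 tested, with 9 not passing (9 and 3 adjusted over the list alone, median 0.32, adjusted p = 7.6e-04), with Oat (1.10 ± 0.11). Female-biased liver genes counted 7 rises and 9 falls of 19 tested, with 3 not passing (7 and 11 adjusted over the list alone, median -0.53, adjusted p = 0.013, adjusted p = 0.23 with an estimated correlation), with Cyp3a44 (-1.78 ± 0.10). The next 2 lists measure RNA and cell handling. Mitochondrially encoded genes counted 2 rises and 0 falls of 13 tested, with 11 not passing (4 and 0 adjusted over the list alone, median 0.39, adjusted p = 3.4e-04, adjusted p = 0.41 with an estimated correlation), with mt-Cytb (0.75 ± 0.19, not past the threshold without TNFa KO 1 with adjusted p = 0.082 or TNFa WT 2 with 0.40 and adjusted p = 0.16) and mt-Atp6 (0.66 ± 0.18, not past the threshold without TNFa KO 1 with adjusted p = 0.088 or TNFa KO 2 with adjusted p = 0.11 or TNFa WT 2 with 0.39 and adjusted p = 0.21). Among all libraries, TNFa WT 2 had the lowest share of values in these genes (2.97%). Immediate-early and isolation stress genes counted 5 rises and 0 falls of 23 tested, with 18 not passing (8 and 1 adjusted over the list alone, median 0.25, adjusted p = 0.0040, adjusted p = 0.10 with an estimated correlation). Fatty acid oxidation enzymes, which break down fatty acids in mitochondria and peroxisomes, did not pass as a list (6 rose and 0 fell of 31, adjusted p = 0.28).

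With TGFb, the KO cells held more message for liver metabolism than the WT cells. The largest rises were in Tspyl5 (a nucleosome assembly family gene near Mtdh, 5.95 ± 0.79) and Hao2 (a peroxisomal hydroxyacid oxidase, 3.43 ± 0.83, not past the threshold without TGFb WT 3 with 2.47 and adjusted p = 0.068, 4.62 without TGFb WT 1). Besides Mtdh, the largest falls were in Sult3a2 (a sulfotransferase with close paralogs, so its reads are uncertain, -3.28 ± 0.88, not past the threshold without TGFb KO 2 with adjusted p = 0.060), Ntrk2 (the BDNF receptor, -2.94 ± 0.62) and Csad (-2.63 ± 0.24). In all, 1764 genes passed, 1048 higher and 716 lower in KO (856 and 477 without TGFb WT 1, 818 and 458 without TGFb WT 3 and 807 and 465 without TGFb KO 1). With each library scaled to an equal total, a setting chosen after the data were seen, the split was 830 higher and 1494 lower, and the median of all genes moved to -0.12. Albumin, the main plasma protein, held 10.1 ± 0.31% of the summed values in KO and 7.71 ± 0.25% in WT libraries (mean and SD of 3).

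Of the fatty acid oxidation enzymes 31 were tested, 21 rose, 0 fell and 10 did not pass (24 and 0 adjusted over the list alone). Their median was 0.49 (list test adjusted p = 2.5e-18), and members that passed included Hadh (0.78 ± 0.09) and Crot (0.69 ± 0.08). Of the fatty acid synthesis genes, which build fatty acids from acetyl-CoA, 23 were tested, 14 rose, 0 fell and 9 did not pass (14 and 1 adjusted over the list alone). Their median was 0.42 (list test adjusted p = 1.8e-09), and members that passed included Acss2 (0.93 ± 0.11) and Thrsp (1.54 ± 0.21). Enzymes of drug and xenobiotic metabolism were higher, and of these 36 were tested, 26 rose, 1 fell and 9 did not pass (27 and 2 adjusted over the list alone). Their median was 0.64 (list test adjusted p = 9.3e-25), and members that passed included Gsta3 (1.31 ± 0.09) and Fmo5 (1.64 ± 0.12). Among hepatocyte identity genes, which mark the differentiated cell, 34 were tested, 19 rose, 1 fell and 14 did not pass (25 and 1 adjusted over the list alone). Their median was 0.55 (list test adjusted p = 3.5e-22), and members that passed included Cps1 (1.38 ± 0.09) and Tdo2 (1.23 ± 0.09).

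Periportal genes were higher as well, and of these 19 were tested, 13 rose, 3 fell and 3 did not pass (15 and 3 adjusted over the list alone). Their median was 0.94 (list test adjusted p = 2.5e-18), and members that passed included Hal (2.42 ± 0.14) and Gls2 (1.56 ± 0.10). Of the bile acid genes with TGFb 26 were tested, 16 rose, 1 fell and 9 did not pass (17 and 2 adjusted over the list alone). Their median was 0.79 (list test adjusted p = 6.4e-14), and members that passed included Akr1d1 (1.46 ± 0.10) and Slco1b2 (1.02 ± 0.08). For glucose production and glycolysis 28 were tested, 14 rose, 0 fell and 14 did not pass (15 and 2 adjusted over the list alone). Their median was 0.30 (list test adjusted p = 8.7e-09, adjusted p = 0.051 with an estimated correlation), and members that passed included Slc2a2 (1.55 ± 0.09) and Pck1 (1.52 ± 0.11). Of nuclear-encoded respiratory chain genes 32 were tested, 11 rose, 0 fell and 21 did not pass (15 and 0 adjusted over the list alone). Their median was 0.33 (list test adjusted p = 8.8e-08), and members that passed included Sdhb (0.85 ± 0.12) and Atp5c1 (0.54 ± 0.11).

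Kupffer cell and macrophage markers were higher here too: 19 were tested, 11 rose, 0 fell and 8 did not pass (13 and 0 adjusted over the list alone). Their median was 1.48 (list test adjusted p = 2.0e-10), and members that passed included Cd5l (2.80 ± 0.21), Lyz2 (1.23 ± 0.13) and Adgre1 (1.94 ± 0.22). Interferon-stimulated genes were lower: 35 were tested, 1 rose, 14 fell and 20 did not pass (2 and 21 adjusted over the list alone). Their median was -0.54 (list test adjusted p = 1.9e-09, adjusted p = 0.10 with an estimated correlation), and members that passed included Parp14 (-1.16 ± 0.11) and Usp18 (-0.78 ± 0.11). For the TNF and NF-kappaB response, a set of inflammatory targets, 29 were tested, 10 rose, 0 fell and 19 did not pass (12 and 1 adjusted over the list alone). Their median was 0.38 (list test adjusted p = 1.1e-05), and members that passed included Tnfrsf1b (0.62 ± 0.09) and Vcam1 (1.13 ± 0.17).

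Lipoproteins and their secretion counted 16 rises and 2 falls of 27 tested, with 9 not passing (18 and 3 adjusted over the list alone, median 0.38, adjusted p = 2.9e-06). Pericentral hepatocyte genes counted 9 rises and 0 falls of 19 tested, with 10 not passing (9 and 1 adjusted over the list alone, median 0.34, adjusted p = 3.3e-07). Triglyceride synthesis, lipid droplets and lipolysis counted 7 rises and 2 falls of 32 tested, with 23 not passing (10 and 2 adjusted over the list alone, median 0.31, adjusted p = 4.2e-04). PPARalpha and ketogenesis targets counted 7 rises and 1 falls of 28 tested, with 20 not passing (11 and 2 adjusted over the list alone, median 0.19, adjusted p = 6.1e-04). Sinusoidal endothelial markers counted 4 rises and 0 falls of 19 tested, with 15 not passing (4 and 0 adjusted over the list alone, median 0.48, adjusted p = 0.011). Immediate-early and isolation stress genes counted 9 rises and 0 falls of 23 tested, with 14 not passing (11 and 2 adjusted over the list alone, median 0.33, adjusted p = 4.2e-04). Mitochondrially encoded genes counted 2 rises and 0 falls of 13 tested, with 11 not passing (4 and 0 adjusted over the list alone, median 0.36, adjusted p = 0.0020, adjusted p = 0.50 with an estimated correlation), with mt-Cytb (0.67 ± 0.19, not past the threshold without TGFb KO 1 with adjusted p = 0.10 or TGFb WT 1 with adjusted p = 0.064 or TGFb WT 3 with adjusted p = 0.093) and mt-Co2 (0.77 ± 0.22, not past the threshold without TGFb KO 1 with adjusted p = 0.11 or TGFb WT 1 with adjusted p = 0.066 or TGFb WT 3 with adjusted p = 0.069). The cholesterol synthesis list did not pass with TGFb (7 rose and 2 fell of 25, adjusted p = 0.077).

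With CM, macrophage and metabolic genes were again higher in KO. The largest rises were in Serpinb1a (an inhibitor of neutrophil proteases, 3.70 ± 0.50) and Tspyl5 (3.49 ± 0.79, 2.12 without CM WT 1, 4.16 without CM WT 2 and 4.20 without CM WT 3). Among the largest falls beside Mtdh were Sult3a2 (-4.65 ± 0.88, -6.06 without CM KO 1 and -3.71 without CM KO 3), Ntrk2 (-3.49 ± 0.62, -4.14 without CM KO 2 and -2.73 without CM KO 3) and Csad (-3.12 ± 0.24). The comparison gave 1358 genes, 813 higher and 545 lower in KO (627 higher and 874 lower with equal totals). Higher and lower counts were 644 and 361 without CM WT 1, 617 and 350 without CM WT 2, 581 and 359 without CM KO 1 and 639 and 357 without CM KO 3. The albumin share was 8.67 ± 0.08% in KO and 6.88 ± 0.07% in WT libraries.

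Of the respiratory chain genes of the nucleus, parts of the mitochondrial ATP supply, 32 were tested, 16 rose, 0 fell and 16 did not pass (19 and 0 adjusted over the list alone). Their median was 0.50 (list test adjusted p = 3.7e-14), and members that passed included Sdhd (0.66 ± 0.10) and Sdhb (0.72 ± 0.12). Of the fatty acid oxidation enzymes with CM 31 were tested, 12 rose, 0 fell and 19 did not pass (15 and 0 adjusted over the list alone). Their median was 0.26 (list test adjusted p = 2.4e-09), and members that passed included Hacl1 (0.89 ± 0.10) and Acaa2 (0.75 ± 0.10). For drug and xenobiotic metabolism 36 were tested, 22 rose, 0 fell and 14 did not pass (25 and 0 adjusted over the list alone). Their median was 0.47 (list test adjusted p = 1.8e-20), and members that passed included Cyp2a5 (1.35 ± 0.09) and Gsta3 (1.10 ± 0.09). For the periportal set 19 were tested, 12 rose, 1 fell and 6 did not pass (15 and 1 adjusted over the list alone). Their median was 0.79 (list test adjusted p = 3.7e-16), and members that passed included Gls2 (1.42 ± 0.10) and Hal (1.91 ± 0.14). For hepatocyte identity 34 were tested, 16 rose, 1 fell and 17 did not pass (17 and 2 adjusted over the list alone). Their median was 0.35 (list test adjusted p = 3.9e-15), and members that passed included Cps1 (1.05 ± 0.09).

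Of the NRF2 antioxidant genes with CM 25 were tested, 7 rose, 0 fell and 18 did not pass (11 and 0 adjusted over the list alone). Their median was 0.27 (list test adjusted p = 1.5e-06), and members that passed included Hmox1 (0.71 ± 0.08) and Gsta2 (2.30 ± 0.30). Gsta2 has a near-identical paralog, so its reads are uncertain. Macrophage markers with CM were higher: 19 were tested, 10 rose, 0 fell and 9 did not pass (14 and 0 adjusted over the list alone). Their median was 1.42 (list test adjusted p = 1.1e-11), and members that passed included Lyz2 (1.42 ± 0.13), Cd5l (1.89 ± 0.21) and Adgre1 (1.40 ± 0.22). Interferon-stimulated genes with CM were lower: 35 were tested, 0 rose, 12 fell and 23 did not pass (0 and 16 adjusted over the list alone). Their median was -0.45 (list test adjusted p = 9.2e-09, adjusted p = 0.12 with an estimated correlation), and members that passed included Stat2 (-0.91 ± 0.16).

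Bile acid synthesis and transport counted 12 rises and 2 falls of 26 tested, with 12 not passing (15 and 2 adjusted over the list alone, median 0.45, adjusted p = 3.8e-08). Lipoproteins and their secretion counted 13 rises and 3 falls of 27 tested, with 11 not passing (15 and 4 adjusted over the list alone, median 0.39, adjusted p = 1.4e-05). Pericentral hepatocyte genes counted 6 rises and 0 falls of 19 tested, with 13 not passing (9 and 0 adjusted over the list alone, median 0.22, adjusted p = 1.0e-05). Glucose production and glycolysis counted 10 rises and 1 falls of 28 tested, with 17 not passing (11 and 1 adjusted over the list alone, median 0.21, adjusted p = 1.0e-07, adjusted p = 0.081 with an estimated correlation). Fatty acid synthesis counted 4 rises and 0 falls of 23 tested, with 19 not passing (9 and 0 adjusted over the list alone, median 0.20, adjusted p = 8.0e-04, adjusted p = 0.094 with an estimated correlation). TNF and NF-kappaB response counted 6 rises and 0 falls of 29 tested, with 23 not passing (7 and 0 adjusted over the list alone, median 0.17, adjusted p = 0.0067), with Tnfaip2 (0.92 ± 0.16). TGF-beta and SMAD targets counted 6 rises and 2 falls of 30 tested, with 22 not passing (8 and 3 adjusted over the list alone, median 0.17, adjusted p = 0.028), with Junb (0.63 ± 0.10). Sinusoidal endothelial markers counted 1 rises and 0 falls of 19 tested, with 18 not passing (1 and 0 adjusted over the list alone, median 0.43, adjusted p = 0.041, adjusted p = 0.075 with an estimated correlation). Immediate-early and isolation stress genes counted 6 rises and 1 falls of 23 tested, with 16 not passing (6 and 2 adjusted over the list alone, median 0.13, adjusted p = 0.028, adjusted p = 0.18 with an estimated correlation).

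Averaged over the 3 treatments (9 KO against 9 WT libraries), the largest rises were in Tspyl5 (4.02 ± 0.46), Lrtm1 (a leucine-rich repeat membrane protein, 2.40 ± 0.41) and Cd5l (a macrophage scavenger protein, 2.33 ± 0.12). Next came Cyp2d9 (a cytochrome P450 with close paralogs, so its reads are uncertain, 2.30 ± 0.24). Besides Mtdh and Csad, Ntrk2 (-2.79 ± 0.36) was among the largest falls. The average passed for 2991 genes, 1614 higher and 1377 lower (1365 higher and 2009 lower with equal totals). In all 3 treatments, 279 genes were higher in KO and 129 were lower, where unrelated sets of those sizes would share 2.47 and 0.999. Another 22 genes passed in opposite directions in 2 treatments.

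Over all 18 libraries, of the macrophage markers 19 were tested, 17 rose, 0 fell and 2 did not pass (17 and 0 adjusted over the list alone). Their median was 1.54 (list test adjusted p = 1.8e-15), and members that passed included Cd5l (2.33 ± 0.12), Lyz2 (1.38 ± 0.07) and Adgre1 (1.54 ± 0.13). Of the endothelial markers 19 were tested, 9 rose, 0 fell and 10 did not pass (13 and 0 adjusted over the list alone). Their median was 0.60 (list test adjusted p = 3.3e-05), and members that passed included Cdh5 (0.73 ± 0.07) and Fcgr2b (1.10 ± 0.18). Markers of other cell types did not pass as lists. Stellate cell and fibroblast markers had 1 higher and 1 lower of 12 (median 0.39, adjusted p = 0.39), with Dcn (0.87 ± 0.14) and Ecm1 (-0.49 ± 0.14). Cholangiocyte markers had 0 higher and 4 lower of 11 (median -0.29, adjusted p = 0.059), with Spp1 (-0.97 ± 0.16) and Sox9 (-0.31 ± 0.08). Lymphocyte markers had 1 higher and 0 lower of 5 (median 0.53, adjusted p = 0.40), with Ptprc (1.07 ± 0.19). Neutrophil markers had 0 higher and 0 lower of 5 (median -0.30, adjusted p = 0.33). Red blood cell genes had 0 higher and 1 lower of 5 (median -1.55, adjusted p = 0.16), with Hbb-bs (-3.12 ± 0.49).

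Drug and xenobiotic metabolism had 28 higher and 1 lower of 36 (median 0.51, adjusted p = 3.1e-21), with Cyp2a5 (1.05 ± 0.05). Periportal hepatocyte genes had 15 higher and 3 lower of 19 (median 0.95, adjusted p = 1.2e-16), with Hal (2.04 ± 0.08). Pericentral hepatocyte genes had 12 higher and 2 lower of 19 (median 0.32, adjusted p = 1.9e-06), with Oat (1.21 ± 0.06). Hepatocyte identity genes had 20 higher and 3 lower of 34 (median 0.28, adjusted p = 1.2e-15), with Cps1 (1.07 ± 0.05). Bile acid synthesis and transport had 17 higher and 2 lower of 26 (median 0.56, adjusted p = 8.0e-11), with Akr1d1 (1.22 ± 0.06). Fatty acid oxidation enzymes had 21 higher and 0 lower of 31 (median 0.30, adjusted p = 1.4e-11), with Hacl1 (0.80 ± 0.06). Nuclear-encoded respiratory chain genes had 21 higher and 0 lower of 32 (median 0.28, adjusted p = 5.8e-09), with Sdhb (0.58 ± 0.07). Fatty acid synthesis had 12 higher and 1 lower of 23 (median 0.19, adjusted p = 8.5e-05, adjusted p = 0.053 with an estimated correlation), with Thrsp (1.01 ± 0.12). Lipoproteins and their secretion had 16 higher and 5 lower of 27 (median 0.24, adjusted p = 3.1e-05).

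PPARalpha and ketogenesis targets had 8 higher and 4 lower of 28 (median 0.18, adjusted p = 0.046, adjusted p = 0.21 with an estimated correlation), with Cd36 (1.21 ± 0.06). Glucose production and glycolysis had 12 higher and 2 lower of 28 (median 0.14, adjusted p = 2.5e-05, adjusted p = 0.15 with an estimated correlation), with Slc2a2 (1.24 ± 0.05). Interferon-stimulated genes had 2 higher and 23 lower of 35 (median -0.45, adjusted p = 2.9e-11, adjusted p = 0.075 with an estimated correlation), with Parp14 (-0.85 ± 0.06). Unfolded protein and amino acid stress response had 2 higher and 10 lower of 27 (median -0.14, adjusted p = 0.0025, adjusted p = 0.078 with an estimated correlation), with Vldlr (-0.38 ± 0.04). NRF2 antioxidant genes had 11 higher and 3 lower of 25 (median 0.15, adjusted p = 4.0e-04), with Gsta2 (2.14 ± 0.17). TNF and NF-kappaB response had 12 higher and 0 lower of 29 (median 0.21, adjusted p = 2.2e-04), with Tnfaip2 (0.88 ± 0.09). Immediate-early and isolation stress genes had 11 higher and 2 lower of 23 (median 0.26, adjusted p = 1.2e-04), with Atf3 (0.52 ± 0.07). Mitochondrially encoded genes had 7 higher and 0 lower of 13 (median 0.36, adjusted p = 2.2e-04, adjusted p = 0.36 with an estimated correlation), with mt-Co3 (0.42 ± 0.08).

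The list test did not pass on average for the remaining lists, although single members did. Triglyceride synthesis, lipid droplets and lipolysis had 8 higher and 5 lower of 32 (median 0.15, adjusted p = 0.070). Cholesterol synthesis had 4 higher and 9 lower of 25 (median -0.06, adjusted p = 0.26). Acute-phase response had 7 higher and 6 lower of 29 (median 0.09, adjusted p = 0.42), with Hamp (the iron hormone hepcidin, with a close paralog, 1.14 ± 0.06). TGF-beta and SMAD targets had 9 higher and 4 lower of 30 (median 0.06, adjusted p = 0.29), with Tgfbr1 (-0.45 ± 0.05). T cell-directed chemokines and checkpoint ligands had 10 higher and 4 lower of 30 (median 0.35, adjusted p = 0.069). Male-biased liver genes had 3 higher and 3 lower of 13 (median 0.01, adjusted p = 0.81), and its median was -0.05 with quantile normalization and -0.02 with equal totals. Female-biased liver genes had 7 higher and 10 lower of 19 (median -0.27, adjusted p = 0.39), with Cyp2b13 (2.17 ± 0.07) and Cyp3a44 (-1.44 ± 0.06).

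Median and mean had opposite signs in the next 4 lists. MHC class I antigen presentation had 5 higher and 6 lower of 24 (median 0.09, adjusted p = 0.99), with H2-Q10 (0.50 ± 0.05). Extracellular matrix and mesenchymal genes had 3 higher and 4 lower of 26 (median -0.02, adjusted p = 0.81), with Lox (a collagen crosslinking enzyme, -1.04 ± 0.08). P53 targets and cell death genes had 6 higher and 2 lower of 28 (median -0.04, adjusted p = 0.73), with Gadd45a (0.56 ± 0.07). Cell cycle had 6 higher and 1 lower of 28 (median 0.07, adjusted p = 0.33), with Rrm2 (-0.38 ± 0.05). Of 17 tested genes listed near Mtdh on chromosome 15, 5 rose, 4 fell and 8 did not pass (list test adjusted p = 0.81). Among them were Rida (1.36 ± 0.05), Vps13b (-0.77 ± 0.05) and Cpq (-0.70 ± 0.07).

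**Figure D2:**
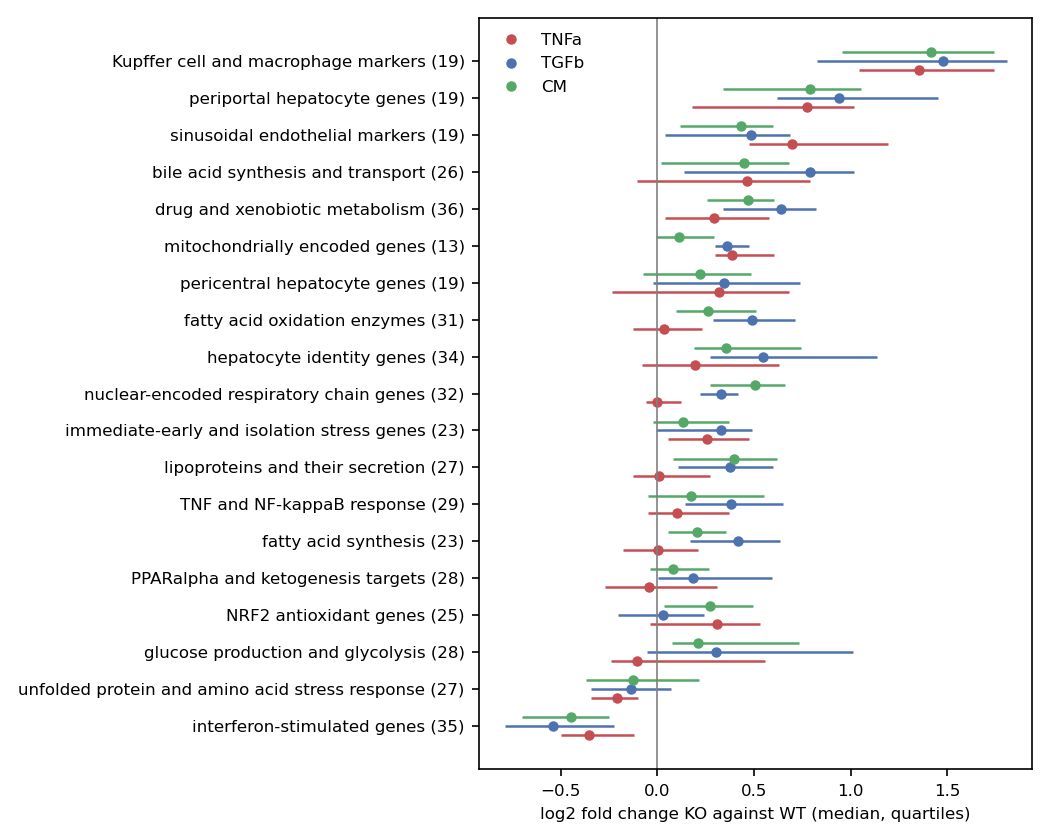
Median and quartiles of the log2 fold change of KO against WT for fixed gene lists, by treatment. Kupffer cell markers had medians of 1.36, 1.48 and 1.42 with TNFa, TGFb and CM.

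The effect of the knockout differed between treatments for some metabolic genes, here with the log2 fold changes under TNFa, TGFb and CM in turn and the adjusted p of the F-test. The smallest p-values belonged to Slc7a2 (a transporter of arginine and lysine, -0.03, 1.27 and 0.33, SE 0.08, adjusted p = 4.1e-07) and Aldh1a1 (a retinal dehydrogenase, 0.23, 1.32 and 0.59, SE 0.09, adjusted p = 2.7e-05). Then came Cldn4 (a tight junction protein, 0.54, 0.03 and 1.10, SE 0.09, adjusted p = 2.2e-04) and Fabp5 (a fatty acid binding protein, -0.66, 0.29 and 0.19, SE 0.10, adjusted p = 6.2e-04). Acaa2, the last enzyme of mitochondrial fatty acid oxidation, had -0.16, 0.69 and 0.75, SE 0.10, adjusted p = 6.2e-04. Further genes were Ep400 (a chromatin remodeller, 0.43, 0.34 and -0.42, SE 0.09, adjusted p = 6.2e-04), Gclc (the first enzyme of glutathione synthesis, 0.65, -0.22 and 0.40, SE 0.09, adjusted p = 0.0011) and Rpl36a (a ribosomal protein with close processed copies, -0.33, 0.20 and 0.92, SE 0.13, adjusted p = 0.0011). The limma F-test of the 2 interaction terms passed for 246 genes. It passed for 118 without TNFa WT 1, 111 without TNFa WT 3, 127 without TNFa KO 1, 140 without TGFb WT 1, 147 without TGFb WT 2, 133 without TGFb WT 3. It further passed for 162 without TGFb KO 1, 160 without TGFb KO 3, 518 without CM WT 3, 130 without CM KO 1, 143 without CM KO 2, 141 without CM KO 3.

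Between TNFa and TGFb, 159 genes differed, 36 with a higher and 123 with a lower KO effect under TNFa (101 higher and 42 lower with equal totals and 55 higher and 86 lower with quantile normalization). Between CM and TNFa the number was 91, 83 with a higher and 8 with a lower KO effect under CM (26 higher and 16 lower with equal totals and 43 higher and 12 lower with quantile normalization). Between CM and TGFb it was 71, 35 with a higher and 36 with a lower KO effect under CM (45 higher and 28 lower with equal totals). Higher and lower counts for TNFa minus TGFb moved without TNFa WT 1 (16 and 55), TNFa WT 3 (16 and 62), TNFa KO 1 (18 and 89), TNFa KO 2 (21 and 87), TGFb WT 1 (16 and 53) and TGFb WT 2 (14 and 72), and without TGFb WT 3 (12 and 71), TGFb KO 1 (16 and 46), TGFb KO 2 (88 and 196) and TGFb KO 3 (25 and 67). Higher and lower counts for CM minus TNFa moved without TNFa WT 1 (42 and 4), TNFa WT 2 (75 and 16), TNFa WT 3 (29 and 4), TNFa KO 1 (30 and 2), TNFa KO 2 (39 and 5) and CM WT 1 (42 and 2), and without CM WT 2 (35 and 3), CM WT 3 (301 and 47), CM KO 1 (41 and 2), CM KO 2 (31 and 5) and CM KO 3 (30 and 4). Higher and lower counts for CM minus TGFb moved without TGFb WT 1 (13 and 8), TGFb WT 2 (14 and 15), TGFb WT 3 (8 and 7), TGFb KO 1 (21 and 19), TGFb KO 3 (10 and 10) and CM WT 1 (13 and 8), and without CM WT 2 (22 and 21), CM WT 3 (165 and 73), CM KO 1 (13 and 14), CM KO 2 (13 and 19) and CM KO 3 (9 and 8).

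As a list, the fatty acid oxidation enzymes gained less in KO cells under TNFa than under TGFb, with 0 higher and 6 lower of 31 (0 and 16 adjusted over the list alone). The median difference was -0.40 (adjusted p = 3.8e-17, and 9.5e-04 with an estimated correlation). A member that passed was Crot (0.24, 0.69 and 0.30, adjusted p = 0.045 for TNFa minus TGFb). The same difference of TNFa minus TGFb passed with both correlations for the next lists. Hepatocyte identity genes had 0 higher and 4 lower of 34 (median -0.36, adjusted p = 3.3e-14). Drug and xenobiotic metabolism had 0 higher and 4 lower of 36 (median -0.33, adjusted p = 2.3e-13). Cholesterol synthesis had 0 higher and 3 lower of 25 (median -0.31, adjusted p = 2.3e-12). Fatty acid synthesis had 0 higher and 4 lower of 23 (median -0.38, adjusted p = 2.4e-12). Glucose production and glycolysis had 0 higher and 3 lower of 28 (median -0.36, adjusted p = 4.0e-10). Female-biased liver genes had 0 higher and 1 lower of 19 (median -0.45, adjusted p = 3.8e-08).

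Nuclear-encoded respiratory chain genes had 0 higher and 1 lower of 32 (median -0.28, adjusted p = 5.6e-08). The lower member was Sdhb (0.16, 0.85 and 0.72, adjusted p = 0.040 for TNFa minus TGFb). Bile acid synthesis and transport had 0 higher and 1 lower of 26 (median -0.33, adjusted p = 1.2e-06). Periportal hepatocyte genes had 0 higher and 3 lower of 19 (median -0.30, adjusted p = 2.0e-06). Triglyceride synthesis, lipid droplets and lipolysis had 0 higher and 5 lower of 32 (median -0.29, adjusted p = 2.6e-06). Lpin1, which makes diacylglycerol, was a member (-0.30, 0.77 and 0.21, adjusted p = 4.7e-04 for TNFa minus TGFb). Lipoproteins and their secretion had 0 higher and 1 lower of 27 (median -0.26, adjusted p = 7.1e-05). Apoa5, a regulator of plasma triglyceride, was a member (0.06, 1.04 and 0.37, adjusted p = 0.0033 for TNFa minus TGFb). PPARalpha and ketogenesis targets had 0 higher and 1 lower of 28 (median -0.26, adjusted p = 9.4e-05). TNF and NF-kappaB response had 0 higher and 2 lower of 29 (median -0.29, adjusted p = 5.6e-04). Pericentral hepatocyte genes had 1 higher and 1 lower of 19 (median -0.15, adjusted p = 0.0062).

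Conversely, the KO effect on the NRF2 antioxidant list was higher under TNFa than under TGFb (3 higher and 0 lower of 25, median 0.08, adjusted p = 0.0071), with Txnrd1 (0.65, 0.16 and 0.54, adjusted p = 0.021 for TNFa minus TGFb). It was also higher under CM than under TGFb (median 0.25, adjusted p = 7.5e-05), with Hmox1 (0.37, 0.05 and 0.71, adjusted p = 0.0036 for CM minus TGFb). For TGF-beta and SMAD targets it was higher under CM as well (median 0.21, adjusted p = 0.0038), with Tgfbr1 (-0.30, -0.87 and -0.17, adjusted p = 0.0016 for CM minus TGFb).

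For CM minus TGFb, 12 lists passed, 2 higher and 10 lower, and with an estimated correlation 2, both of the higher ones. The lower ones follow. Bile acid synthesis and transport had 0 higher and 0 lower of 26 (median -0.25, adjusted p = 1.1e-04, adjusted p = 0.11 with an estimated correlation). Hepatocyte identity genes had 0 higher and 0 lower of 34 (median -0.24, adjusted p = 1.1e-04, adjusted p = 0.18 with an estimated correlation). Fatty acid oxidation enzymes had 0 higher and 2 lower of 31 (median -0.14, adjusted p = 1.6e-04, adjusted p = 0.093 with an estimated correlation). Fatty acid synthesis had 0 higher and 1 lower of 23 (median -0.23, adjusted p = 4.8e-04, adjusted p = 0.18 with an estimated correlation). Periportal hepatocyte genes had 0 higher and 1 lower of 19 (median -0.26, adjusted p = 0.0031, adjusted p = 0.18 with an estimated correlation). Drug and xenobiotic metabolism had 0 higher and 0 lower of 36 (median -0.16, adjusted p = 0.012, adjusted p = 0.37 with an estimated correlation). Cholesterol synthesis had 0 higher and 1 lower of 25 (median -0.11, adjusted p = 0.024, adjusted p = 0.54 with an estimated correlation). Female-biased liver genes had 0 higher and 0 lower of 19 (median -0.35, adjusted p = 0.024, adjusted p = 0.41 with an estimated correlation). Glucose production and glycolysis had 0 higher and 3 lower of 28 (median -0.25, adjusted p = 0.024, adjusted p = 0.57 with an estimated correlation). Triglyceride synthesis, lipid droplets and lipolysis had 0 higher and 1 lower of 32 (median -0.26, adjusted p = 0.024, adjusted p = 0.27 with an estimated correlation).

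For CM minus TNFa, 12 lists passed, 11 higher and 1 lower, and with an estimated correlation 0. Nuclear-encoded respiratory chain genes had 2 higher and 0 lower of 32 (median 0.46, adjusted p = 8.1e-13, adjusted p = 0.062 with an estimated correlation). Drug and xenobiotic metabolism had 3 higher and 0 lower of 36 (median 0.18, adjusted p = 9.2e-06, adjusted p = 0.11 with an estimated correlation). Cholesterol synthesis had 1 higher and 0 lower of 25 (median 0.27, adjusted p = 9.2e-06, adjusted p = 0.18 with an estimated correlation). Fatty acid oxidation enzymes had 2 higher and 0 lower of 31 (median 0.17, adjusted p = 9.2e-06, adjusted p = 0.062 with an estimated correlation). The list of glucose production and glycolysis had 0 higher and 0 lower of 28 (median 0.22, adjusted p = 2.8e-04, adjusted p = 0.27 with an estimated correlation). Hepatocyte identity genes had 0 higher and 0 lower of 34 (median 0.14, adjusted p = 4.7e-04, adjusted p = 0.24 with an estimated correlation). Fatty acid synthesis had 1 higher and 0 lower of 23 (median 0.17, adjusted p = 6.6e-04, adjusted p = 0.18 with an estimated correlation). The list of lipoproteins and their secretion had 0 higher and 0 lower of 27 (median 0.20, adjusted p = 0.0014, adjusted p = 0.13 with an estimated correlation). Female-biased liver genes had 0 higher and 0 lower of 19 (median 0.22, adjusted p = 0.0042, adjusted p = 0.24 with an estimated correlation). Sinusoidal endothelial markers had 0 higher and 0 lower of 19 (median -0.54, adjusted p = 0.0071, adjusted p = 0.073 with an estimated correlation). Acute-phase response had 0 higher and 0 lower of 29 (median 0.17, adjusted p = 0.018, adjusted p = 0.32 with an estimated correlation). Triglyceride synthesis, lipid droplets and lipolysis had 1 higher and 0 lower of 32 (median 0.14, adjusted p = 0.022, adjusted p = 0.24 with an estimated correlation).

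For TNFa minus TGFb, 23 lists passed, 4 higher and 19 lower, and 16 with an estimated correlation. The lists that passed with the fixed correlation alone follow. Acute-phase response had 0 higher and 0 lower of 29 (median -0.13, adjusted p = 0.0062, adjusted p = 0.19 with an estimated correlation). Male-biased liver genes had 0 higher and 0 lower of 13 (median -0.39, adjusted p = 0.021, adjusted p = 0.058 with an estimated correlation). Interferon-stimulated genes had 1 higher and 0 lower of 35 (median 0.18, adjusted p = 0.022, adjusted p = 0.51 with an estimated correlation). Extracellular matrix and mesenchymal genes had 0 higher and 0 lower of 26 (median 0.33, adjusted p = 0.022, adjusted p = 0.11 with an estimated correlation). Sinusoidal endothelial markers had 0 higher and 0 lower of 19 (median 0.46, adjusted p = 0.028, adjusted p = 0.052 with an estimated correlation). MHC class I antigen presentation had 0 higher and 0 lower of 24 (median -0.13, adjusted p = 0.043, adjusted p = 0.19 with an estimated correlation). Neutrophil markers had 0 higher and 0 lower of 5 (median -3.83, adjusted p = 0.049, adjusted p = 0.11 with an estimated correlation).

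The series holds no untreated library, so each treatment in WT cells was set against another. TNFa against TGFb raised Tmem171 (a membrane protein, 4.18 ± 0.87, 3.44 without TGFb WT 1 and 5.05 without TGFb WT 2), Gvin1 (an interferon-induced GTPase with close paralogs, 3.86 ± 0.69, 2.41 without TGFb WT 1 and 5.29 without TGFb WT 2) and Crct1 (a cornified envelope gene, 3.60 ± 0.40) most. Among the largest falls were Mroh4 (a HEAT repeat gene, -7.01 ± 1.09) and Hr (a histone demethylase, -5.09 ± 0.79, -5.98 without TNFa WT 1, -3.48 without TNFa WT 2 and -5.82 without TNFa WT 3). In total 1936 genes passed, 771 higher and 1165 lower under TNFa. With equal totals the split was 1366 higher and 873 lower, and the median of all genes moved to 0.11.

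Of the TNF and NF-kappaB response genes 29 were tested, 14 rose, 1 fell and 14 did not pass (17 and 1 adjusted over the list alone). Their median was 0.76 (list test adjusted p = 4.5e-12), and members that passed included Ccl2 (3.36 ± 0.17), Cxcl1 (1.97 ± 0.17) and Tnfaip3 (0.90 ± 0.10). Of the interferon-stimulated genes under TNFa 35 were tested, 24 rose, 0 fell and 11 did not pass (29 and 0 adjusted over the list alone). Their median was 0.75 (list test adjusted p = 3.1e-17), and members that passed included Parp14 (0.86 ± 0.11) and Usp18 (0.79 ± 0.11). Of NRF2 antioxidant genes under TNFa 25 were tested, 12 rose, 2 fell and 11 did not pass (15 and 2 adjusted over the list alone). Their median was 0.43 (list test adjusted p = 7.8e-11), and members that passed included Txnrd1 (0.88 ± 0.08) and Gsta1 (2.68 ± 0.25). Gsta1 is uncertain because it shares reads with a paralog. The TGF-beta and SMAD targets lay on the TGFb side: 30 were tested, 3 rose, 14 fell and 13 did not pass (5 and 18 adjusted over the list alone). Their median was -0.59 (list test adjusted p = 2.5e-08), and members that passed included Tgfbr1 (-1.50 ± 0.08), Pmepa1 (-2.51 ± 0.17) and Ccn2 (-1.38 ± 0.11).

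Hepatocyte identity genes were lower under TNFa than under TGFb: 34 were tested, 1 rose, 23 fell and 10 did not pass (1 and 26 adjusted over the list alone). Their median was -0.52 (list test adjusted p = 3.1e-17), and members that passed included Tdo2 (-0.98 ± 0.09) and Ahsg (-0.93 ± 0.10). Fatty acid oxidation enzymes were lower as well: 31 were tested, 0 rose, 19 fell and 12 did not pass (0 and 24 adjusted over the list alone). Their median was -0.47 (list test adjusted p = 2.1e-15), and members that passed included Crot (-0.98 ± 0.08) and Hadh (-0.86 ± 0.09). Pericentral genes, near the central vein, were lower too: 19 were tested, 0 rose, 13 fell and 6 did not pass (0 and 15 adjusted over the list alone). Their median was -0.72 (list test adjusted p = 3.9e-15), and members that passed included Cyp1a2 (-1.03 ± 0.10) and Glul (-1.16 ± 0.11). Drug and xenobiotic metabolism had 3 higher and 23 lower of 36 (median -0.56, adjusted p = 5.8e-15). Periportal hepatocyte genes had 0 higher and 12 lower of 19 (median -0.47, adjusted p = 6.4e-11). Female-biased liver genes had 0 higher and 13 lower of 19 (median -0.69, adjusted p = 7.8e-11).

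Bile acid synthesis and transport had 1 higher and 16 lower of 26 (median -0.51, adjusted p = 6.1e-11), with Slco1b2 (-1.30 ± 0.08). Lipoproteins and their secretion had 2 higher and 14 lower of 27 (median -0.47, adjusted p = 6.4e-08). Acute-phase response had 4 higher and 15 lower of 29 (median -0.54, adjusted p = 6.8e-08), with Hamp (-1.27 ± 0.10). PPARalpha and ketogenesis targets had 3 higher and 15 lower of 28 (median -0.61, adjusted p = 2.4e-07). Male-biased liver genes had 0 higher and 5 lower of 13 (median -0.49, adjusted p = 5.6e-05). Glucose production and glycolysis had 3 higher and 11 lower of 28 (median -0.14, adjusted p = 0.0049, adjusted p = 0.36 with an estimated correlation). Extracellular matrix and mesenchymal genes had 2 higher and 7 lower of 26 (median -0.24, adjusted p = 0.022, adjusted p = 0.14 with an estimated correlation), with S100a6 (-1.61 ± 0.14). Cholesterol synthesis had 8 higher and 1 lower of 25 (median 0.15, adjusted p = 4.2e-04, adjusted p = 0.18 with an estimated correlation). Kupffer cell and macrophage markers had 5 higher and 1 lower of 19 (median 0.25, adjusted p = 0.018, adjusted p = 0.18 with an estimated correlation), with Slc40a1 (0.82 ± 0.11).

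In WT cells, genes of liver metabolism were higher with CM than with TNFa. The largest rises were in Apoc2l (3.63 ± 0.95, not past the threshold without CM WT 3 with adjusted p = 0.059), Gpr137c (a lysosomal membrane protein, 2.58 ± 0.49) and Fam20a (a secretory pathway pseudokinase, 2.25 ± 0.42). Apoc2l lies beside Apoc2, so its reads are uncertain. Among the genes that fell was Rab39b (a small GTPase, -2.82 ± 0.85, not past the threshold without CM WT 1 with -1.01 and adjusted p = 0.31 or TNFa WT 1 with adjusted p = 0.062 or TNFa WT 2 with adjusted p = 0.055 or TNFa WT 3 with adjusted p = 0.081, -3.70 without CM WT 2 and -3.75 without CM WT 3). The comparison gave 1774 genes, 985 higher and 789 lower with CM (857 higher and 1062 lower with equal totals, 802 and 453 without TNFa WT 3).

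Of the hepatocyte identity genes with CM 34 were tested, 21 rose, 0 fell and 13 did not pass (26 and 0 adjusted over the list alone). Their median was 0.54 (list test adjusted p = 1.9e-18), and members that passed included Tat (1.30 ± 0.10) and Tdo2 (1.03 ± 0.09). Of the fatty acid oxidation enzymes in this comparison 31 were tested, 20 rose, 0 fell and 11 did not pass (23 and 2 adjusted over the list alone). Their median was 0.42 (list test adjusted p = 2.3e-17), and members that passed included Crot (1.27 ± 0.08) and Acsl1 (1.18 ± 0.09). Bile acid genes with CM were higher: 26 were tested, 17 rose, 0 fell and 9 did not pass (18 and 0 adjusted over the list alone). Their median was 0.57 (list test adjusted p = 1.2e-16), and members that passed included Slco1b2 (1.42 ± 0.08) and Slco1a4 (1.31 ± 0.10). Cholesterol synthesis genes with CM were higher: 25 were tested, 17 rose, 0 fell and 8 did not pass (19 and 1 adjusted over the list alone). Their median was 0.43 (list test adjusted p = 1.8e-14), and members that passed included Cyp51 (0.80 ± 0.09) and Stard4 (0.72 ± 0.09). The acute-phase response, plasma proteins made in inflammation, was higher with CM: 29 were tested, 18 rose, 1 fell and 10 did not pass (19 and 1 adjusted over the list alone). Their median was 0.40 (list test adjusted p = 1.5e-12), and members that passed included Hamp (1.27 ± 0.10) and Steap4 (1.39 ± 0.12).

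Drug and xenobiotic metabolism had 20 higher and 2 lower of 36 (median 0.45, adjusted p = 1.1e-13). Female-biased liver genes had 11 higher and 0 lower of 19 (median 0.75, adjusted p = 1.6e-11). Fatty acid synthesis had 12 higher and 1 lower of 23 (median 0.46, adjusted p = 1.1e-10). PPARalpha and ketogenesis targets had 13 higher and 2 lower of 28 (median 0.44, adjusted p = 5.1e-09). Pericentral hepatocyte genes had 8 higher and 0 lower of 19 (median 0.52, adjusted p = 4.8e-08). Periportal hepatocyte genes had 10 higher and 2 lower of 19 (median 0.49, adjusted p = 5.7e-08). Lipoproteins and their secretion had 12 higher and 1 lower of 27 (median 0.36, adjusted p = 2.4e-05). Glucose production and glycolysis had 11 higher and 2 lower of 28 (median 0.17, adjusted p = 9.0e-04, adjusted p = 0.27 with an estimated correlation), with Pck1 (1.71 ± 0.11).

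Male-biased liver genes had 3 higher and 0 lower of 13 (median 0.70, adjusted p = 0.0016). Triglyceride synthesis, lipid droplets and lipolysis had 7 higher and 1 lower of 32 (median 0.20, adjusted p = 0.010, adjusted p = 0.12 with an estimated correlation). Interferon-stimulated genes had 0 higher and 7 lower of 35 (median -0.24, adjusted p = 4.9e-05, adjusted p = 0.27 with an estimated correlation), with Usp18 (-0.64 ± 0.11). NRF2 antioxidant genes had 1 higher and 4 lower of 25 (median -0.13, adjusted p = 0.0013), with Srxn1 (-0.67 ± 0.08). TGF-beta and SMAD targets had 1 higher and 4 lower of 30 (median -0.11, adjusted p = 0.038), with Junb (-0.66 ± 0.10). The TNF and NF-kappaB response did not pass (4 rose and 7 fell of 29, adjusted p = 0.067). Within it, Nfkbiz (1.23 ± 0.14) rose and Ccl2 (-1.10 ± 0.17) fell.

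CM against TGFb in WT cells raised Ccl6 (a chemokine, 4.61 ± 0.72, 5.38 without TGFb WT 2 and 3.47 without TGFb WT 3), Ivl (a cornified envelope protein, 4.36 ± 0.44), Gvin1 (4.23 ± 0.69, 2.78 without TGFb WT 1 and 5.66 without TGFb WT 2) and Crct1 (4.16 ± 0.40) most. Among the largest falls were Adgra1 (an adhesion receptor, -6.97 ± 0.99) and Mroh4 (-6.36 ± 1.09, -7.01 without CM WT 2). It gave 1712 genes, 832 higher and 880 lower with CM (1102 higher and 626 lower with equal totals).

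Of the cholesterol synthesis genes with CM against TGFb 25 were tested, 21 rose, 0 fell and 4 did not pass (21 and 0 adjusted over the list alone). Their median was 0.63 (list test adjusted p = 1.0e-25), and members that passed included Lss (1.37 ± 0.12) and Hmgcs1 (0.91 ± 0.09). Of the fatty acid synthesis genes 23 were tested, 9 rose, 1 fell and 13 did not pass (11 and 1 adjusted over the list alone). Their median was 0.28 (list test adjusted p = 1.3e-07), and members that passed included Elovl6 (1.32 ± 0.10) and Acacb (1.46 ± 0.14). The TNF and NF-kappaB response was higher with CM than with TGFb: 29 were tested, 12 rose, 0 fell and 17 did not pass (14 and 1 adjusted over the list alone). Their median was 0.38 (list test adjusted p = 1.2e-08), and members that passed included Cxcl1 (2.30 ± 0.17) and Ccl2 (2.26 ± 0.17). TGF-beta and SMAD targets were again on the TGFb side: 30 were tested, 3 rose, 16 fell and 11 did not pass (3 and 19 adjusted over the list alone). Their median was -0.59 (list test adjusted p = 3.4e-13), and members that passed included Tgfbr1 (-1.66 ± 0.08) and Pmepa1 (-2.79 ± 0.17).

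Interferon-stimulated genes had 10 higher and 0 lower of 35 (median 0.45, adjusted p = 1.7e-06, adjusted p = 0.35 with an estimated correlation), with Rigi (0.81 ± 0.12). NRF2 antioxidant genes had 8 higher and 2 lower of 25 (median 0.31, adjusted p = 1.6e-04), with Slc7a11 (0.96 ± 0.11). Pericentral hepatocyte genes had 0 higher and 6 lower of 19 (median -0.25, adjusted p = 0.0019), with Cyp2a5 (-0.47 ± 0.09). Immediate-early and isolation stress genes had 0 higher and 4 lower of 23 (median -0.15, adjusted p = 0.020, adjusted p = 0.27 with an estimated correlation), with Junb (-1.40 ± 0.10). Extracellular matrix and mesenchymal genes had 3 higher and 6 lower of 26 (median -0.18, adjusted p = 0.042, adjusted p = 0.29 with an estimated correlation), with S100a6 (-2.35 ± 0.14). Nuclear-encoded respiratory chain genes had 0 higher and 4 lower of 32 (median -0.11, adjusted p = 0.042, adjusted p = 0.61 with an estimated correlation). Mtdh itself did not pass between treatments in WT cells. Its log2 fold changes were -0.06 for TNFa against TGFb, -0.17 for CM against TNFa and -0.23 for CM against TGFb, the first 0.017 with quantile normalization and 0.053 with equal totals.

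**Figure D3:**
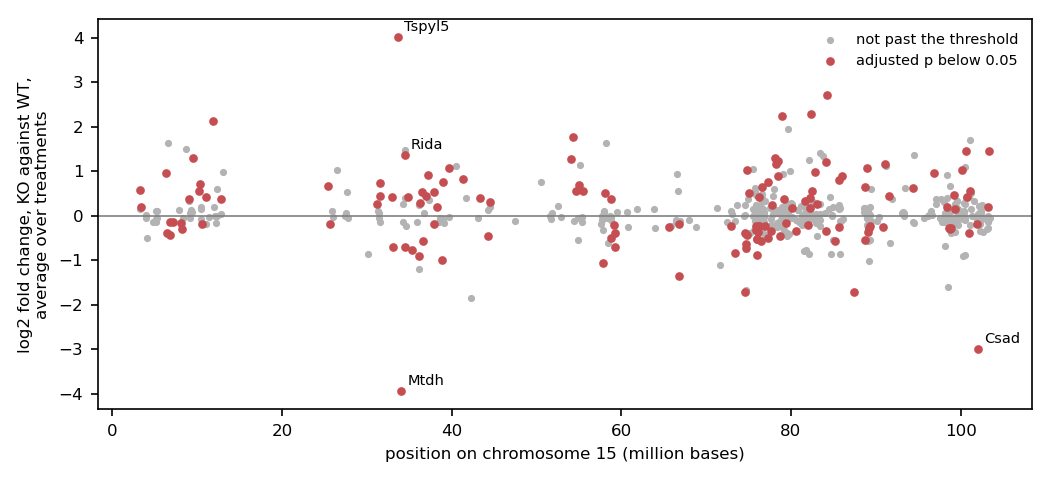
Log2 fold change of KO against WT, averaged over treatments, along chromosome 15. Within 5 Mb of Mtdh, 21 of 40 other tested genes passed.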

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

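The tests that weigh explanations below, and the counts of other splits, were chosen only after the results were seen. The results in this paragraph and the next stand here because a limma test of the difference of the KO effect between treatments passed. The F-test passed for 246 genes, and the pairwise tests passed for 159 genes (TNFa minus TGFb), 91 (CM minus TNFa) and 71 (CM minus TGFb). Genes named in the report or by the naming rule that passed the F-test included, with adjusted p, Slc7a2 (4.1e-07), Aldh1a1 (2.7e-05), Cldn4 (2.2e-04), Acaa2, Ep400 and Fabp5 (6.2e-04 each), Gclc, Lox, Lpin1, Rpl36a and Tgfbr1 (0.0011 each) and Slc40a1 (0.0035). Next were Acss2 (0.0041), Apoa5 and Hmox1 (0.0052 each), Slc25a1 (0.0053), Pklr (0.0063), Junb and Pcna (0.014 each) and Cyp2b10 (0.016). These were followed by F10, Fdps and Parp14 (0.017 each), Slc7a11 (0.018), Vim (0.019), Cps1 (0.021), Lpin2 and Pck1 (0.023 each) and Stard4 (0.024). Then came Slc1a4, Fosb, Sesn2 and Txnrd1 (0.027 each), Sult2a1 (0.028), Acsl1 (0.030), Gls2 (0.031), Nnt, Slc2a2 and Abca1 (0.032 each) and Gng2 (0.038). After these came Bid and Btg2 (0.039 each), Cyp2a5 (0.041), Cnn2 and Trib3 (0.042 each), Sfn (0.043), S100a6 (0.046) and Mup3, Ddit4 and Sdhb (0.047 each). Last were Atp5c1, Crot, Gpam, Sdhd and Serpina3m (0.049 each).

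Lists that passed with both correlations for TNFa minus TGFb were, with adjusted p, fatty acid oxidation enzymes (3.8e-17), hepatocyte identity genes (3.3e-14), drug and xenobiotic metabolism (2.3e-13), cholesterol synthesis (2.3e-12), fatty acid synthesis (2.4e-12) and glucose production and glycolysis (4.0e-10). Further ones were female-biased liver genes (3.8e-08), nuclear-encoded respiratory chain genes (5.6e-08), bile acid synthesis and transport (1.2e-06), periportal hepatocyte genes (2.0e-06) and triglyceride synthesis, lipid droplets and lipolysis (2.6e-06). The list test also passed for lipoproteins and their secretion (7.1e-05), PPARalpha and ketogenesis targets (9.4e-05), TNF and NF-kappaB response (5.6e-04), pericentral hepatocyte genes (0.0062) and NRF2 antioxidant genes (0.0071). For CM minus TGFb the lists were NRF2 antioxidant genes (7.5e-05) and TGF-beta and SMAD targets (0.0038). Medians of these differences were below 0 for TNFa minus TGFb except for the NRF2 antioxidant genes.

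Other splits of the libraries were fitted with the same model. Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05, and only the real one reached the real count. KO against WT gave 1141 genes with TNFa (highest other split 0), 1764 with TGFb (highest other 2) and 1358 with CM (highest other 0). Between treatments in WT the counts were 1936 for TNFa against TGFb, 1774 for CM against TNFa and 1712 for CM against TGFb (highest other 0 each). If libraries are independent, chance is argued against as follows. For KO against WT on average, 1 of 100 splits, the real one, reached 2991 genes (highest other 186). For a KO effect that differs between treatments, 1 of 100, the real one, reached 246 (highest other 7). If treatments share mice, the average has 10 splits, too few.

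Kupffer cell and endothelial markers were higher in KO libraries, with all KO libraries above all WT libraries in mean Kupffer marker level in each of 3 treatments, and abundant markers such as Lyz2 had a mean value of 622 in WT and 1761 in KO with TNFa. A lower share of hepatocytes would raise the markers of other cell types alike. Against it as the whole cause, the Kupffer median exceeded that of 31 endothelial and stellate markers by 0.96 (95% interval 0.68 to 1.34). Intervals here resampled markers, taken as independent, not libraries. Kupffer cells carried over with the conditioned medium are argued against by a median of 1.36 (1.18 to 1.56) with TNFa, where no such medium was added, and by WT medians of -0.20 for CM against TNFa and 0.01 for CM against TGFb. More RNA from Kupffer cells in KO preparations is an explanation that stays open. That 17 of 19 tested markers were called higher and 0 lower restates the pattern and gives this explanation no support of its own. A change of these genes within other cells stays open too. No biological explanation was tested, and no sort against Kupffer cells is given in the sources.

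Genes around Mtdh on chromosome 15 were called more often than genes elsewhere, with 21 of 40 tested genes within 5 Mb called on average (52.5%). Of 44 genes 2 to 10 Mb away, 19 were called (43.2%) against 20.6% elsewhere (exact test p = 6.4e-04, genes taken as independent). Of blocks with as many genes as the 5 Mb window, 0 of 349 elsewhere reached 52.5% (highest 45%, median 20%). If genes are independent, 43.2% argues against nearest neighbours alone. A block elsewhere reached 45%, so a local effect of the edit stays open. DNA of another strain linked to the edited gene also stays open, since the shares cannot tell causes apart. The strain is not given in the sources, and changes of genes such as Tspyl5, Rida and Vps13b might belong to the region, not to the loss of Mtdh.

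Fatty acid oxidation enzymes gained less in KO with TNFa than with TGFb, with a median difference of -0.40 (quartiles -0.50 to -0.28) and 30 of 31 members below 0. A single deviating library is argued against by the weakest median without 1 of the 12 libraries, -0.36. Scaling of libraries with unequal shares of the most abundant genes is argued against as the whole cause by a median of -0.26 with equal totals, although part of the difference went with it. Transcript length and GC content had a trend that held 1.41% of the variance and moved the middle 95% of genes by -0.18 to 0.24, and the median was -0.39 after it was removed. They are argued against as the whole cause because genes matched in both had a median of -0.02 (95% of 2000 draws, -0.19 to 0.17), and 0 draws reached the list. A response to the treatments that depends on Mtdh is a hypothesis that stays open, found and tested on the same libraries, beside differences in cell state or composition between the preparations.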

How the results depend on the processing

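Equal totals, limma-voom and library weights were chosen after seeing the data, and the other settings were planned. DESeq2 and edgeR were not run because whole reads were not recovered. The cause of a change was not tested unless stated. Counts of called genes for KO against WT (1141 with TNFa, 1764 with TGFb, 1358 with CM, 2991 on average) and between treatments in WT (1936, 1774 and 1712) stayed within 1.5 times in the alternatives except those of only the groups compared, which gave 719 for KO against WT with TNFa, 795 with CM and 904 for CM against TNFa in WT. That alternative has fewer samples to estimate the spread.

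Counts for the difference of the KO effect moved more. No filter gave 105 for TNFa minus TGFb (main 159), 44 for CM minus TNFa (main 91), 47 for CM minus TGFb (main 71) and 150 for the F-test (main 246), with more genes tested. For CM minus TNFa, quantile normalization gave 55, equal totals 42, limma-voom 186 and library weights 207. Library weights further gave 313 for TNFa minus TGFb and 439 for the F-test. With an estimated correlation, the lists that passed fell from 14 to 8 for KO against WT with TNFa, from 10 to 6 for CM against TGFb in WT, from 12 to 0 for CM minus TNFa (7 with an unadjusted camera p below 0.05) and from 12 to 2 for CM minus TGFb. Mtdh for TNFa against TGFb in WT (main -0.06, not called) reversed to 0.017 with quantile normalization and 0.053 with equal totals.

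With 1 library left out, KO against WT ranged from 783 to 922 genes with TNFa, 1272 to 1731 with TGFb, 940 to 1478 with CM and 2725 to 2963 on average. Between treatments in WT the ranges were 1562 to 1665 (TNFa against TGFb), 1255 to 1811 (CM against TNFa) and 1213 to 1676 (CM against TGFb). They were 62 to 284 for TNFa minus TGFb, 32 to 348 for CM minus TNFa, 15 to 238 for CM minus TGFb and 111 to 518 for the F-test. Of 724 named gene and comparison pairs, 613 kept their call without each library and 111 lost it without at least 1.

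The replicate number as a block gave 1049, 1654, 1272 and 2893 genes for KO against WT with TNFa, TGFb, CM and on average, 1859, 1693 and 1637 between treatments in WT, 109, 69 and 51 for the pairwise differences and 182 for the F-test. It ended 7 of the 724 named calls and 1 list call. In 4 of 18 libraries the best correlation of deviations was with the own number, and pairs with the same number had correlations from -0.07 to 0.05, a hint from the data, not the design. A correlation within genotype and number (estimated as 0.00588) ended 0 of the 724. Means per genotype and replicate number gave 2750 genes on average.

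The other settings ended named calls as follows: 14 each with quantile normalization and equal totals, 9 with library weights, 1 with median-of-ratios scaling, 2 with a pseudocount of 0.5, 0 with 5, 23 with no filter, 22 with limma-voom and 82 with only the groups compared. Of the named genes left by a filter on a mean of at least 50, 0 lost their call. List calls ended 11 times with quantile normalization (10 were gained) and 10 times with equal totals (6 were gained). At depths between 19.4 and 35.6 M reads small changes can be missed, and in simulated data 29 of 50 genes changed 1.5-fold and 48 of 50 changed 4-fold were found for KO against WT with TNFa, against 11 and 46 of 50 for the interaction.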

Other observations

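Genotype effects of the 3 treatments were related across genes with correlations of 0.27 (TNFa and TGFb), 0.22 (TNFa and CM) and 0.26 (TGFb and CM). The treatments share no libraries but may share mice. With TGFb, Sult2a5 (2.80 ± 0.48) and Cd5l (2.80 ± 0.21) were further large rises. On average Cyp2b13 (2.17 ± 0.07) and Gsta2 (2.14 ± 0.17) were among the genes that rose most, both with close paralogs that leave their reads uncertain. Between treatments in WT, Ccl2 (3.36 ± 0.17) was among the largest rises of TNFa against TGFb, Bex2 (-4.70 ± 0.53) among its largest falls, and Cd163 (3.54 ± 0.83, 4.32 without TGFb WT 3) among the largest rises of CM against TGFb.

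Albumin held 6.20% of the values with TNFa in WT and 6.11% in KO libraries.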
